A study of Homo sapiens with 4 samples.

How the data were processed

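Poly(A) RNA was measured by sequencing in AC16 cells at 0, 10, 30 and 360 min in 10 nM doxorubicin, with 1 library per time point. Per the labels' protocols, the medium with serum was removed, the cells were rinsed and the drug was given in serum-free medium. The cells were later detached with trypsin, RNA was extracted with Trizol and purified on poly(dT) beads, and cDNA was made with a SmartScribe kit. Per the submitters' processing notes, HISAT2, DESeq2 and the GRCh38 assembly were used, with no versions. The counting tool, the annotation release and whether strand was used are not given in the sources used here.

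The authors deposited estimated counts per gene and per transcript, neither scaled nor divided by length. The values are whole numbers, so rounding changed nothing. In each library the gene counts and the transcript counts have the same total. Of all counts, 99.7% lie in loci that carry only an assembly identifier, which points to transcripts assembled across the libraries. Transcript models made by the assembly, not annotated, hold 11.1% of counts. The deposited values cover 66839 loci and 230349 transcripts.

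Low values of loci with a single transcript piled up at multiples of 4: 32.1% of 7006 values from 1 to 24, where even spacing gives 25%. Values also piled up at 2 (893 values, against 487 at 1 and 601 at 3), so the worth of a read pair is not settled by them. A read pair was taken as worth about 4 deposited counts, the more cautious choice, and counting intervals and floors used the count divided by 4. This departs from the plan made before the data were examined, and undivided counts, which give narrower intervals, were run as an alternative. The libraries hold 55156612 to 56875881 counts, or 13789153 to 14218970 read pairs on this scale. No molecular identifiers are recorded in the labels, so intervals and floors cover counting error only.

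An assembly locus was given a gene's name where its 4 counts, less those of its own assembled models, equalled the summed counts of that gene's annotated transcripts in GENCODE 29, with a total of at least 20 counts. A locus that matched a run of up to 6 neighbouring genes took the name of a gene with at least 95% of its counts. This named 15348 loci by 1 gene and 687 by a dominant gene, which together with loci that carry gene identifiers hold 87.6% of counts. As a check, neighbours in assembly order lay on 1 chromosome in 99.6% of cases (15975 pairs), and 82.6% of those pairs were in genome order. Named values are those of the whole locus, including assembled models. TOP2B and MDM2 had no locus of their own, and their annotated transcripts were summed and scaled with TMM factors of the summed transcripts. Neither is among the measured members of a gene list.

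Values were scaled to CPM with TMM factors from edgeR 4.0.16 in R 4.3.3 (0.991, 1.03, 0.988 and 0.990 at 0, 10, 30 and 360 min). Each pair of libraries was compared by the ratio of these CPM with a 95% exact (Clopper-Pearson, conditional binomial) interval from SciPy 1.17.1. A locus passed the size rule at 2-fold or more, with at least 5 CPM in 1 of the 2 libraries and an interval that excluded 1. A library with 0 counts entered its ratio at a floor of 3 read pairs (12 counts). With 1 library per group neither edgeR's quasi-likelihood test nor DESeq2's test was run, no p-value was computed, and each comparison is of libraries, not of conditions. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

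The named genes follow a rule set before the data were examined. At each time they are the 12 increases and 12 decreases past the size rule with at least 10 CPM, a gene symbol and the largest folds at the interval bound nearest to 1, up to 4 members of each described list with the largest absolute log2 ratio and at least 5 CPM, and up to 10 genes past the rule in the same direction at all 3 times. TOP2A, TOP2B, TOP1, CDKN1A and MDM2 are always named. A few genes that meet these rules are left out of the text. Genes antisense to another, those with near copies and those whose exons share at least 10% of bases with another gene are called uncertain, the last as a check added after the data were seen.

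Before the data were examined, 35 gene lists were fixed, among them markers of cardiomyocytes, fibroblasts and extracellular matrix, endothelium, immune cells and epithelium. A list's measured members had at least 1 CPM in 1 or more libraries. The median log2 ratio was given as a percentile among 10000 random lists of the same size matched in 20 bins of mean expression, as a description of these libraries. A list with fewer than 3 measured members got no median.

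The size rule and the random-list percentile were tested on simulated libraries. Library scaling was taken as known, and the naming of loci and the sharing of reads among models were not simulated. Wrong calls from those steps are therefore not counted here. For 10 against 0 min, with counting noise only, the size rule called 50 of 50 genes changed 3-fold and 23 of 50 changed 2-fold. It called 0 of 50 changed 1.5-fold and 0 of 11663 unchanged genes. With an added coefficient of variation of 0.1 it called 49 of 50, 29 of 50, 3 of 50 and 4 of 11711. The 95% intervals covered the true ratio for 95.4% of unchanged genes with counting noise only but for 57.4% with the added variation, so they are too narrow where libraries vary by more than counting. Of 200 lists of 25 genes drawn at random from the measured 10 min ratios, 11 fell outside the middle 95% of random lists. When shifted by 0.5 on the log2 scale, 186 of 200 such lists did. The draws come from the same values as the random lists, so the first share is near its level by construction. They do not cover lists whose members vary together.

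Alternatives were total counts or median-of-ratios factors (DESeq2 1.42.0) in place of TMM, other minimum levels and fold thresholds, 1 CPM added to both libraries, genes with symbols only, mitochondrial and ribosomal protein genes left out before scaling, transcripts summed per gene, and another baseline for lists. Added after the data were seen were undivided counts, loci with the same leading transcript model in both libraries, and scaling without the 10 min library. Y-linked genes and XIST were not reported.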

Results

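AC16 is an established human cell line, made by fusing adult ventricular heart cells with transformed fibroblasts and labelled a cardiomyocyte line. It was exposed to doxorubicin at 10 nM, an anthracycline that intercalates into DNA and traps topoisomerase II on it, for 10, 30 or 360 min, and 1 untreated library served as 0 min. The design asks how the transcriptome moved over the course of the exposure. RNA was sequenced from 1 library at each of the 4 times, so no difference has a replicate check and no p-value was computed. A range after a fold or a ratio is its 95% counting interval, which covers counting error only. Bootstrap ranges resample genes, and no interval covers variation between libraries. The deposited gene counts summed to 56875881, 55596712, 55278725 and 55156612 at 0, 10, 30 and 360 min, worth about 14218970, 13899178, 13819681 and 13789153 read pairs. Treated cells were also moved from serum-containing to fresh serum-free medium, and the labels do not say whether the 0 min cells were, so each comparison with 0 min holds the drug, the medium change and the loss of serum together.

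Loci that passed the size rule (at least 2-fold, at least 5 CPM in 1 of the 2 libraries, and a 95% counting interval that excluded 1) were most numerous at the shortest exposure. At 10 min, 641 of 12131 compared loci were higher and 670 lower than at 0 min. These were 754 and 572 with total counts in place of TMM and 673 and 642 with median-of-ratios factors, so which direction held more loci depended on the scaling. At 30 min the numbers were 197 higher and 163 lower of 11808, and at 360 min 113 higher and 130 lower of 11741.

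**Figure D1:**
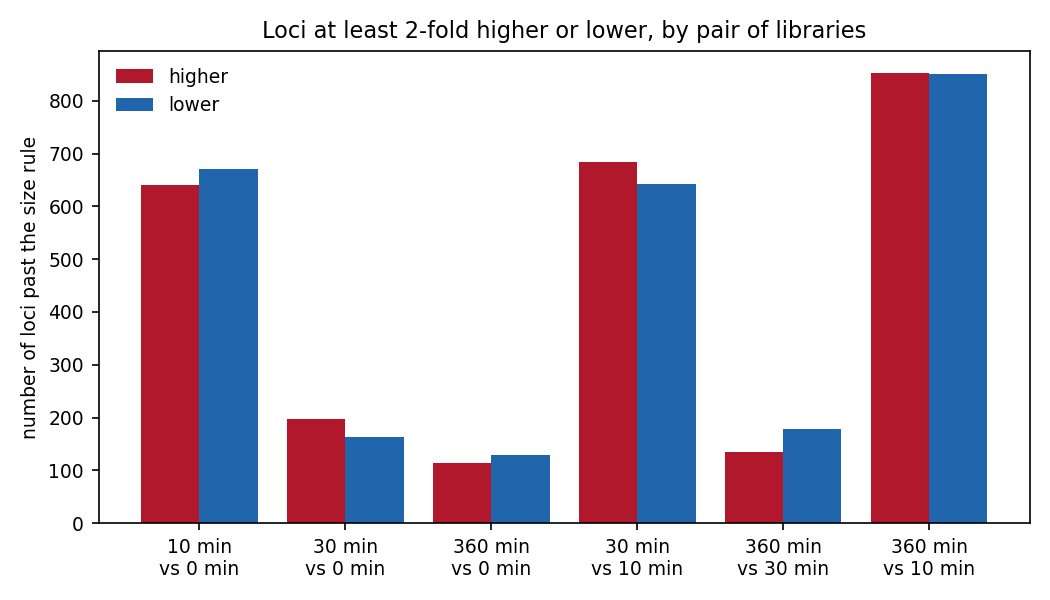
Number of loci past the size rule (vertical axis) for each pair of libraries (horizontal axis), higher in red and lower in blue in the first-named library. The 3 pairs that contain the 10 min library hold at least 1311 loci each, and the other 3 pairs at most 360.

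In the 10 min library, genes of DNA replication and mitosis were low, and immediate early, hypoxia, FOXO and circadian genes were high as lists. TXNIP, an arrestin-family regulator of glucose uptake and thioredoxin (ENSG00000265972, chromosome 1, 145992435 to 145996600, GRCh38 with GENCODE 29 annotation), was 12.8-fold (10.2 to 16.04) higher, from 5.92 to 75.6 CPM. The immediate early transcription factor EGR1 (ENSG00000120738, chromosome 5, 138465490 to 138469315) was 12.4-fold (10.0 to 15.4) higher, and FOS was 20.4-fold (8.70 to 54.2) higher from 0.408 CPM. RRM2, the small subunit of ribonucleotide reductase (ENSG00000171848, chromosome 2, 10120698 to 10131419), fell from 246 to 60.4 CPM, 4.07-fold (3.77 to 4.39) lower. TOP2A, the topoisomerase II form of dividing cells and a target of doxorubicin (ENSG00000131747, chromosome 17, 40388516 to 40417950), was 2.25-fold (2.16 to 2.34) lower, from 595 to 265 CPM.

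Among the 12 leading increases at 10 min were also DAG1, which encodes dystroglycan (9.50-fold, 8.45 to 10.8), YPEL2 (13.8-fold, 8.14 to 24.1), the small GTPase gene RAB8B (6.33-fold, 5.57 to 7.23) and KLF16, a Krüppel-like transcription factor (6.20-fold, 4.97 to 7.80). DAG1 lies at chromosome 3, 49468703 to 49535618 (ENSG00000173402), RAB8B at chromosome 15, 63189469 to 63267782 (ENSG00000166128) and KLF16 at chromosome 19, 1852399 to 1863568 (ENSG00000129911). ADNP2 (5.82-fold), PCMTD1 (5.90-fold), MAP1S (5.17-fold) and the host gene MIR3936HG (8.97-fold) completed the list with MSC-AS1 (6.95-fold) and SYT15B (6.89-fold), which are uncertain because MSC-AS1 is antisense and SYT15B has a near copy. The leading decreases were ZBTB38, a methyl-DNA-binding zinc finger protein (6.34-fold, 5.73 to 7.04), KPNA6, an importin alpha (5.77-fold, 5.16 to 6.46), POLR1G, a subunit of RNA polymerase I (6.17-fold, 4.98 to 7.83), the mitochondrial ribosomal protein gene MRPL34 (5.80-fold, 4.66 to 7.30; ENSG00000130312, chromosome 19, 17292609 to 17306843) and ATF5 (5.70-fold, 4.41 to 7.43). CCDC137, ARMC6, the cytokine gene IL11, the proteasome activator gene PSME3, the kinetochore gene ZWINT and FAM111B were 4.65 to 5.10-fold lower. The most counted transcript model of the locus differed between the libraries for 4 of these 12 increases (DAG1, MIR3936HG, MSC-AS1 and MAP1S) and for 7 of the 12 decreases (ZBTB38, KPNA6, POLR1G, ATF5, ARMC6, PSME3 and RRM2). Because strand use in counting is not stated, genes whose exons share at least 10% of their bases with a gene on the other strand are less certain: here KLF16 (16.3%), POLR1G (43.5%, with ERCC1), ATF5 (21.2%, with NUP62) and MRPL34 (13.2%, with ABHD8). RRM2 shares 20.2% with an annotated gene on its own strand.

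The G1/S and DNA replication list had a median log2 ratio of -1.48 at 10 min, with 22 of its 26 measured members lower and 0 higher. The cyclin gene CCNE2 (4.84-fold, 3.49 to 6.68), the checkpoint mediator CLSPN (4.14-fold, 3.51 to 4.89), E2F2 (4.11-fold, 3.20 to 5.36) and the replication initiation gene MCM10 (4.09-fold, 3.38 to 4.98) were the lowest. Of 27 measured G2/M and mitosis genes 21 were lower (median -1.19), among them CDC20 (3.03-fold), KIF11 (2.99-fold), CCNB1 (2.98-fold) and CCNA2 (2.71-fold). Ribosome biogenesis genes had a median of -1.003 with 11 of 21 lower, including RRP12 (2.75-fold), POLR1C (2.58-fold), UTP20 (2.53-fold) and NOP16 (2.43-fold). All 3 medians lay below all 10000 random lists matched on expression.

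DNA double-strand break repair genes were also low at 10 min (median -0.66, percentile 0), with 8 of 26 lower, such as BLM (3.85-fold), BRCA2 (3.49-fold) and H2AX (2.97-fold). In the heat shock list 4 of 12 members were lower (median -0.61, percentile 0.12): the chaperone genes HSPH1 (2.72-fold), HSPA8 (2.52-fold), HSP90AA1 (2.40-fold) and DNAJA1 (2.37-fold). Topoisomerase and tyrosyl-DNA phosphodiesterase genes had a median of -0.54 (percentile 3.96), inside the middle 95% of random lists (-0.59 to 0.31), and TOP2A was the only 1 of 7 past the rule. TOP1 stood at a ratio of 0.702 (0.655 to 0.752) and TOP2B, not among the 7, at 0.933 (0.881 to 0.989).

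Immediate early genes had a median of 0.50 (percentile 100) at 10 min, with 6 of 30 higher, including the mRNA decay factor gene ZFP36 (3.54-fold, 2.80 to 4.54) and MYC (2.27-fold, 2.02 to 2.56). Hypoxia response genes had a median of 0.60 (percentile 100), with 6 of 20 higher and 1 lower, among them the glycolytic enzyme genes ENO2 (3.91-fold) and ALDOC (3.11-fold), NDRG1 (2.99-fold) and the mitophagy receptor gene BNIP3L (2.68-fold), all higher. In the list of FOXO and growth factor withdrawal genes (median 0.47, percentile 99.96), 6 of 15 were higher, with TXNIP above BCL6 (3.54-fold) and GABARAPL1 (2.75-fold), while PDK4 was lower (2.43-fold). The circadian output list (median 0.58, percentile 99.9) had 3 of 13 higher, NR1D1 (4.94-fold, 3.81 to 6.42), DBP (3.74-fold, 2.90 to 4.80) and TEF (2.02-fold, 1.69 to 2.43).

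Beside these groups, fibroblast and extracellular matrix markers had a median of 0.44 (percentile 99.99) at 10 min, with none of 17 members past the rule and LOX highest at a ratio of 1.64 (1.55 to 1.74). Cardiomyocyte markers had a median of 0.06 (percentile 66.8), with none of 12 past the rule. For p53 targets the median was 0.21 (percentile 99.6), with GDF15 higher (3.41-fold) and the phosphatase gene PPM1D lower (2.07-fold). NF-kB and cytokine genes had a median of -0.32 (percentile 9.21), with ICAM1 higher (3.03-fold) and IL11 lower. The 10 min library had counts at 29129 loci against 27461 at 0 min, 27314 at 30 min and 27353 at 360 min. Of its 641 higher loci, 233 stayed below 5 CPM in all other libraries.

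**Figure D2:**
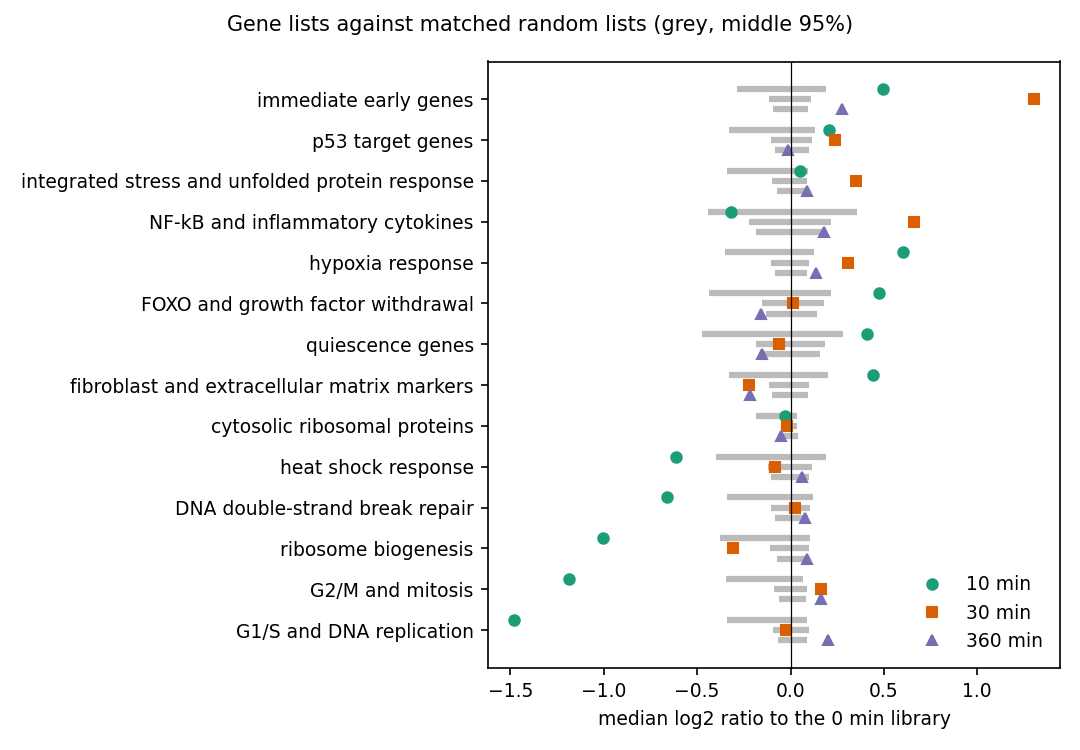
Median log2 ratio to the 0 min library (horizontal axis) of the measured members of 14 gene lists (vertical axis) at 10 min (circles), 30 min (squares) and 360 min (triangles), with the middle 95% of 10000 expression-matched random lists as grey bars. The replication and mitosis lists lie at -1.48 and -1.19 at 10 min and between -0.02 and 0.20 later, and the immediate early genes reach 1.30 at 30 min.

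At 30 min, 15 of 30 measured immediate early genes were higher and 0 lower (median 1.30, percentile 100). EGR1 reached 430.2 CPM, 64.0-fold (52.1 to 79.0) above 0 min, and FOS (ENSG00000170345, chromosome 14, 75278774 to 75282230) reached 24.4 CPM, 59.9-fold (26.1 to 158) above it. DUSP1, a MAP kinase phosphatase (ENSG00000120129, chromosome 5, 172768090 to 172771195), rose from 166 to 660.4 CPM (3.98-fold, 3.80 to 4.16), and the Krüppel-like factor KLF2 was 7.33-fold (5.75 to 9.53) higher. SPRY4 (8.10-fold, 5.50 to 11.9) and SPRY2 (5.24-fold, 3.82 to 7.500), inhibitors of receptor tyrosine kinase signalling, were also higher.

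The other leading increases at 30 min were SNX22, MIR3936HG (10.2-fold), KLF16 (6.94-fold), RAB8B (5.13-fold), ATP6V0E2 (4.31-fold) and the m6A reader gene YTHDF2 (3.88-fold). SNX22 rested on 0.0887 CPM at 0 min, which leaves its ratio of 132 (29.2 to 6564) with little precision. The leading decreases included NSMCE3 of the SMC5/6 complex (11.4-fold, 8.34 to 16.2), TMEM164 (5.43-fold, 4.71 to 6.24), MRPL34 (5.16-fold, 4.16 to 6.42), MDM4 (5.78-fold, 4.13 to 8.31) and B2M, the light chain of MHC class I (4.25-fold, 3.97 to 4.55). CHST11, ZNF260, the nuclear receptor gene PPARA and IGFN1 were 4.25 to 5.24-fold lower, as were, less certainly because they are antisense genes, VIM-AS1 (7.97-fold) and ZNF503-AS2 (5.39-fold). The leading transcript model differed between the libraries for 5 of the 12 increases (SNX22, FOS, MIR3936HG, ATP6V0E2 and YTHDF2) and 7 of the 12 decreases (NSMCE3, VIM-AS1, TMEM164, MDM4, B2M, ZNF503-AS2 and PPARA). ATP6V0E2 shares 12.8% of its exon bases with an antisense gene.

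**Figure D3:**
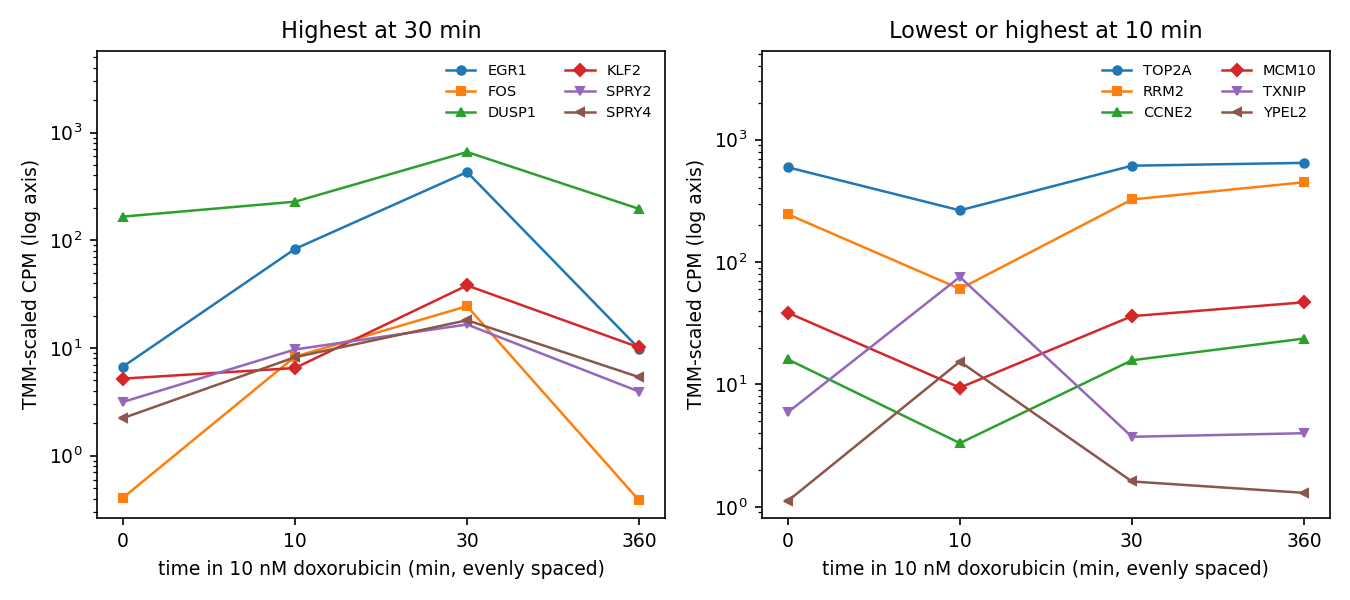
TMM-scaled CPM (vertical axis, log scale) of 12 genes in the single libraries at 0, 10, 30 and 360 min (horizontal axis, evenly spaced), each point 1 library with no replicate. EGR1 runs through 6.72, 83.2, 430.2 and 9.86 CPM, and TOP2A through 595, 265, 613 and 647 CPM.

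Other groups had smaller medians at 30 min. NF-kB and inflammatory cytokine genes had a median of 0.66 (percentile 100), with 3 of 13 higher: the chemokine CXCL8 (7.34-fold, 4.02 to 13.4), NFKBIZ (2.81-fold, 2.35 to 3.40) and LIF (2.07-fold, 1.79 to 2.38), while IL11 stood at a ratio of 0.579 (0.537 to 0.625). Of 17 serum response factor and YAP targets 4 were higher (median 0.17, percentile 99.94), the matricellular genes CCN2 (2.51-fold) and CCN1 (2.43-fold), ANKRD1 (2.41-fold) and AMOTL2 (2.21-fold). The integrated stress and unfolded protein list (median 0.35, percentile 100) had 2 of 24 higher, PPP1R15A (2.55-fold) and the amino acid transporter SLC7A5 (2.10-fold). Hypoxia genes had a median of 0.31 (percentile 99.99) with ENO2 (3.14-fold), BNIP3L (2.72-fold) and VEGFA (2.39-fold) higher. Ribosome biogenesis (-0.31, percentile 0) and TGF-beta and BMP targets (-0.25, percentile 0.03) had low medians with none of 21 and 17 members past the rule, and UTP20 was at 0.642 (0.587 to 0.700).

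For p53 targets the 30 min median was 0.24 (percentile 99.99), with 2 of 31 higher, the stress cytokine GDF15 (3.33-fold, 2.49 to 4.45) and GADD45A (2.54-fold, 2.35 to 2.76). CDKN1A, the p21 cell cycle inhibitor, stood at a ratio of 1.44 (1.37 to 1.51). The ubiquitin ligase gene MDM2, not among the 31, stood at 1.48 (1.36 to 1.61), and both were short of the rule. Extracellular matrix markers had a median of -0.22 (percentile 0.03) with none of 17 past the rule, and COL1A2 at 0.687 (0.668 to 0.706). Among cardiomyocyte markers (median 0.06, percentile 74.1), NPPB, the gene of B-type natriuretic peptide, was the only 1 of 12 past the rule (3.30-fold, 2.99 to 3.64 higher). Circadian output genes had a median of 0.15 (percentile 92.6) with NR1D1 higher (2.74-fold), and FOXO genes 0.01 (percentile 51.8) with PDK4 lower (2.22-fold). Replication and mitosis genes had medians of -0.02 (percentile 34.6) and 0.16 (percentile 99.96), with GINS1 alone past the rule (2.60-fold lower). With annotated transcripts summed per gene in place of loci, 426 genes were higher and 389 lower at 30 min.

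At 360 min no list median lay farther than 0.28 from 0 on the log2 scale, and no immediate early gene was higher. DAG1 (10.7-fold, 9.56 to 12.1), ADNP2 (7.02-fold, 5.75 to 8.65), KLF16 (6.01-fold, 4.82 to 7.58) and RAB8B (5.72-fold, 5.03 to 6.54) led the increases, and LPCAT2, a lysophosphatidylcholine acyltransferase (ENSG00000087253, chromosome 16, 55508998 to 55586670), the decreases (25.7-fold, 12.5 to 76.7, from 12.2 to 0.476 CPM). EGR1 was at 9.86 CPM and FOS at 0.385 CPM. Of 28 immediate early genes 1, MAFF, was lower (2.16-fold, 1.76 to 2.69), although the list's median was 0.28 (percentile 100). That median became -0.28 when the baseline was the median of the other 3 libraries.

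Further increases at 360 min were the neurosecretory gene VGF (3.51-fold, 3.14 to 3.92), SPIN1 (3.39-fold, 3.10 to 3.70), the transcription factor gene CREB3L2 (3.38-fold, 3.10 to 3.69) and TSN, which encodes translin (3.60-fold, 3.08 to 4.19). TUBA1B-AS1 (4.27-fold) and RN7SL2 (4.49-fold) are uncertain, the former as an antisense gene and the latter as a copy of the 7SL RNA gene. CHP1 (4.01-fold higher) and SP1 (3.74-fold higher) went the other way, to log2 ratios of -2.02 and -1.85, when annotated transcripts were summed in place of the locus, and VAT1 (3.69-fold lower) went to 0.0960. Decreases also included FAM217B (7.19-fold, 5.10 to 10.6), ZNF264 (5.67-fold, 4.11 to 8.005), MRPL34 (5.06-fold, 4.08 to 6.29), PPARA (3.90-fold, 3.26 to 4.71), BCL2L11, the pro-apoptotic BIM gene (4.60-fold, 3.15 to 7.01), and the guanylate cyclase subunit gene GUCY1A2 (3.98-fold, 3.02 to 5.27). GINS1, FLG, MAGEC1 and the antisense gene VIM-AS1 were 2.70 to 5.11-fold lower. The leading model differed between the libraries for 6 of the 12 increases (DAG1, ADNP2, TUBA1B-AS1, CHP1, SP1 and TSN) and 4 of the 12 decreases (ZNF264, VAT1, BCL2L11 and FLG). BCL2L11 shares 10.9% of its exon bases with a gene on the other strand, MIR4435-2HG.

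Replication and mitosis genes, low at 10 min, had medians of 0.20 (percentile 100) and 0.16 (percentile 100) at 360 min, with GINS1 the only member past the rule in either list and RRM2 at a ratio of 1.83 (1.75 to 1.90). Hypoxia genes had a median of 0.14 (percentile 99.8), with BNIP3L (2.55-fold) and ENO2 (2.03-fold) higher, and that median was -0.0592 against the other 3 libraries. NF-kB and cytokine genes (0.18, percentile 97.8) had 1 of 13 higher, the adhesion gene ICAM1 (2.01-fold, 1.34 to 3.06). Among apoptosis regulators (median 0.06, percentile 80.8), BCL2L11 was lower and CFLAR, which encodes FLIP, was higher (2.34-fold, 1.97 to 2.80). The p53 target median was -0.01 (percentile 32.5) with none of 31 past the rule and CDKN1A at 1.05 (1.00 to 1.11). MDM2, not among the 31, was at 1.07 (0.978 to 1.17).

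DNA double-strand break repair genes had medians of 0.02 (percentile 68.4) at 30 min and 0.08 (percentile 93.8) at 360 min, with none of 26 past the rule at either time. TOP2A stood at 1.09 (1.05 to 1.12), TOP2B at 1.01 (0.957 to 1.07) and TOP1 at 1.02 (0.960 to 1.09) at 360 min, and the topoisomerase list at -0.07 (percentile 22.3) and -0.08 (percentile 15.1) at 30 and 360 min. FOXO and growth factor withdrawal genes had a median of -0.16 (percentile 1.11), with GABARAPL1 higher (2.13-fold) and PIK3IP1 (2.08-fold) and TRIB2 (2.05-fold) lower. Extracellular matrix markers (-0.22, percentile 0) and cardiomyocyte markers (-0.25, percentile 0.73) lay low beside them with no member past the rule, and the cardiomyocyte median was 0.00625 among members with an unchanged leading model. With annotated transcripts summed per gene, 388 genes were higher and 402 lower.

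Over the whole course, 30 loci were higher and 13 lower than at 0 min at all 3 times. KLF16 held 40.9, 45.8 and 39.7 CPM against 6.60 CPM, and RAB8B 121, 98.4 and 109.7 against 19.2 CPM. MRPL34 stayed at 6.63, 7.45 and 7.60 CPM against 38.4, and PPARA at 18.6, 10.0 and 10.9 against 42.7. DAG1, the zinc finger gene ZNF267, SPRY4, PCMTD1 and CREB3L2 were the other leading genes that were higher throughout. SUCLG2-DT was also higher throughout as a locus, but its annotated transcripts summed to log2 ratios of -6.51, -2.08 and -2.61. All these share the single 0 min library, so an unusual value there would give the same pattern.

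Between the 10 and 30 min libraries, mitosis genes were higher at 30 min, 26 of 27 by the size rule (median 1.31, percentile 100). So were 21 of 26 replication genes (median 1.43, percentile 100). This step starts from the same single 10 min library, and against 0 min the 30 min medians were 0.16 and -0.02. It is therefore no second observation of a change in these lists. Immediate early genes had a median of 0.80 (percentile 100) with 6 of 30 higher, and FOXO genes -0.58 (percentile 0) with 3 of 15 lower. In all, 683 loci were higher and 642 lower in this step, and 594 and 762 with total counts in place of TMM. Of the 670 loci lower at 10 min, 556 (83.0%) lay within 1.5-fold of 0 min at 30 min, as did 404 (63.0%) of the 641 that were higher. The same share over all loci was not computed. Of all 11808 loci compared at 30 min, 1182 passed the rule at 1.5-fold, which also needs an interval that excludes 1. Lying near 0 min was thus common among all loci. The 670 and 641 loci were chosen for lying at least 2-fold from 0 min at 10 min, so most differed less from 0 min at 30 min. This was so for a smaller share of the higher loci than of the lower ones. A return over time and an unusual 10 min library cannot be told apart here. From 30 to 360 min, 11 of 30 immediate early genes fell (median -1.09, percentile 0) and ribosome biogenesis genes had a median of 0.40 (percentile 100) with none of 21 past the rule. That step held 135 higher and 179 lower loci, and the 360 and 10 min libraries differed at 852 and 851.

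Overlaps were counted among loci compared at both times, which leaves out part of the loci past the size rule at 1 time. Of 11649 loci compared at both 30 and 360 min, with 148 and 99 higher and 163 and 130 lower, 49 were higher at both times and 39 lower at both, MRPL34, PPARA, KLF16 and RAB8B among them. Independent lists would share 1.26 and 1.82, and simulated unchanged libraries that share a simulated 0 min library shared 0.19 and 0.07 on average. For 10 and 30 min, with 395 and 164 higher and 670 and 163 lower among 11698 loci, the shared numbers were 75 and 48 (independent 5.54 and 9.34, simulated 0.19 and 0.04), and for 10 and 360 min, with 375 and 97 higher and 670 and 130 lower among 11651, 49 and 23 (independent 3.12 and 7.48, simulated 0.18 and 0.12). Part or all of each excess may come from the shared 0 min library. Across 12295 loci, which are not independent replicates, the log2 ratios to 0 min correlated at Pearson's r = 0.52 (Spearman's rho 0.45) between 30 and 360 min, 0.37 (rho 0.28) between 10 and 30 min and 0.13 (rho -0.02) between 10 and 360 min. Unchanged libraries were simulated around the mean of all libraries, with an assumed coefficient of variation of 0.1 and a shared simulated 0 min library. They gave r of about 0.50 for each pair, since the control is shared. The simulated overlaps and covariances depend on that assumed variation. The covariances were 0.106, 0.120 and 0.0380 in that order, against simulated 0.0288, 0.0289 and 0.0289. The ratios of 10 to 0 min and of 360 to 30 min, which share no library, correlated at -0.27 (rho -0.31).

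Single transcripts passed the size rule more often than loci. The numbers higher and lower were 4677 and 5178 of 25065 at 10 min, 4145 and 3949 of 24667 at 30 min and 3950 and 3833 of 24509 at 360 min. In 1278, 1288 and 1258 genes respectively, 1 transcript was higher while another was lower. These numbers depend on how reads were shared among the models of a locus, which the deposited tables do not show.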

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

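The tests of exchanged labels and of mRNA decay in this part were chosen after the results were seen. Every difference between time points given here is untested, because each time has 1 library.

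Lists whose medians lay above the middle 95% of random lists at 1 time and below it at another were singled out. The G1/S and DNA replication median was 1.68 higher (log2) at 360 than at 10 min. The G2/M and mitosis median was 1.35 higher at 30 than at 10 min and 1.35 higher at 360 than at 10 min. FOXO and growth factor withdrawal genes were 0.63 higher at 10 than at 360 min, and quiescence genes 0.57 higher. Fibroblast and extracellular matrix markers were 0.66 higher at 10 than at 30 min and 0.66 higher than at 360 min, and cholesterol synthesis genes 0.28 higher at 10 than at 30 min. Of single loci, 5 passed the size rule in opposite directions at 10 and 30 min (ADAMTS14, FBXO34, PODNL1, SPIN1 and 1 without a name, named here after their values were seen), and 14 did at 10 and 360 min.

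The low replication and mitosis genes of the 10 min library were weighed further. A GC content or transcript length trend does not account for it, since the G1/S median was still -1.39 (bootstrap -1.65 to -1.19) after that trend over 13831 loci was taken off, from -1.48 before. Decay of existing mRNA alone would need a half-life of 6.76 min at the list's median. Without new synthesis, decay would leave these genes lower still at later times. The G1/S median was instead -0.02 at 30 min and 0.20 at 360 min, with 1 of 26 members lower at each. The G2/M median was 0.16 at both times, with 0 of 27 lower. These values, from 1 library per time, argue against lasting decay in these lists. A brief fall made good by 30 min stays open, since no half-lives were measured. An exchange of the 10 and 360 min labels cannot be told apart from a true early difference: the idea came from the numbers of loci past the size rule against 0 min, 243 at 360 min, 360 at 30 min and 1311 at 10 min, so these do not test it, and FOS (8.32, 24.4 and 0.385 CPM at 10, 30 and 360 min, from 0.408 CPM) and the 6 of 30 immediate early genes higher at 10 min, with 0 of 28 at 360 min, run as the labels say without excluding it. Another culture state of the 10 min cells, and an effect of 10 min in drug and fresh serum-free medium, remain open and untested.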

How the results depend on the processing

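The alternatives with undivided counts, with loci of an unchanged leading transcript model and with scaling that left out the 10 min library were chosen after the results were seen. No paired analysis was possible because each time has 1 library, and for the same reason no library could be left out of a group. Of 98 counts of loci under alternatives, 54 stayed within 1.5 times the reported count, including all under other scaling, undivided counts, symbols only, 1 CPM added, mitochondrial and ribosomal protein genes left out, and scaling without the 10 min library. Even so, total counts in place of TMM turned the balance of directions, to 754 higher and 572 lower for 10 against 0 min and 594 and 762 for 30 against 10 min. Median-of-ratios factors turned it for 10 against 0 min (673 and 642) but not for 30 against 10 min (671 and 653). Undivided counts left the numbers against 0 min exactly as reported at each time (641 and 670 at 10 min). They therefore do not test what a read pair is worth. Of 605 list medians 586 kept to within the distance from centre to edge of the random lists' middle 95%, and of 1828 log2 ratios of named genes 1728 stayed inside their counting interval. The cause was not tested for any of the changes below, except that looser or stricter thresholds admit more or fewer loci by construction. Depth limits genes with few read pairs most, such as SNX22 at 0.0887 and FOS at 0.408 CPM at 0 min.

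At 1.5-fold the higher and lower loci were 1586 and 2064 at 10 min, 610 and 572 at 30 min and 392 and 462 at 360 min against 0 min, 1987 and 1571 for 30 against 10 min and 481 and 585 for 360 against 30 min. At 3-fold they were 192 and 127, 57 and 46, 38 and 32, 141 and 216 and 36 and 46 in the same order. With a minimum of 1 CPM they were 1626 and 1082 at 10 min, 523 and 584 at 30 min and 369 and 500 at 360 min, with 20 CPM 250 and 466, 98 and 79 and 67 and 48, and with no minimum level 2554 and 1598, 1070 and 1085 and 836 and 1012. Transcript counts summed per gene gave 426 and 389 at 30 min and 388 and 402 at 360 min, and 901 and 884 at 10 min. Loci with an unchanged leading model alone gave 95 lower at 30 min and 66 and 86 at 360 min.

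Against the median of the other 3 libraries, the 360 min medians turned to -0.28 for immediate early genes, -0.0592 for hypoxia response and -0.0299 for glycolysis. The cardiomyocyte median at 360 min turned to 0.00625 with members of an unchanged leading model. With transcripts summed per gene, log2 ratios turned to -2.02 for CHP1, -1.85 for SP1 and 0.0960 for VAT1 at 360 min, and to -6.51, -2.08 and -2.61 for SUCLG2-DT at 10, 30 and 360 min. At 20 CPM or more, correlations were 0.0970 for 10 with 360 min, 0.50 for 30 with 360 min and -0.33 for the pair without a shared library. Transcripts higher and lower at that level were 1598 and 1996 at 10 min, 1471 and 1411 at 30 min and 1452 and 1373 at 360 min.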

Other observations

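The tests of leading transcript models and of gene length in this part were fixed before their results were seen. The comparison with loci whose leading model held at least 90% of counts was added afterwards.

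Few members of the other metabolic and stress lists passed the rule. Autophagy and lysosome genes had medians of 0.22 (percentile 99.5), 0.03 (percentile 71.3) and -0.08 (percentile 2.99) at 10, 30 and 360 min, with GABARAPL1 alone past the rule. Cholesterol synthesis genes had medians of 0.15 (percentile 99.1), -0.13 (percentile 0.64) and 0.02 (percentile 66.6) with no member past the rule and INSIG1 at a ratio of 1.84 (1.73 to 1.96) at 10 min. Glycolysis genes stood at 0.04 (percentile 87.9), 0.16 (percentile 99.92) and 0.09 (percentile 98.0), with ENO2 higher at each time and ALDOC at 10 min, and the 360 min median turned to -0.0299 against the median of the other 3 libraries. The NRF2 list stood at -0.12 (percentile 53.8), 0.03 (percentile 76.6) and -0.01 (percentile 34.2), and the cystine transporter SLC7A11 was the only member past the rule (2.29-fold, 2.15 to 2.45 higher at 30 min), as in the ferroptosis and iron list (0.03, percentile 86.1, 0.05, percentile 80.8 and 0.06, percentile 85.1). Quiescence genes had medians of 0.41 (percentile 99.5), -0.06 (percentile 23.9) and -0.15 (percentile 2.14), with CDKN1C higher at 10 min (2.37-fold) and GAS1 lower at 30 min (2.96-fold). Interferon-stimulated genes stood at 0.40 (percentile 97.7), 0.17 (percentile 95.4) and -0.05 (percentile 31.6), with STAT2 (2.30-fold) and MX2 (2.15-fold) higher at 10 min.

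Cytosolic ribosomal proteins had medians of -0.03 (percentile 72.0), -0.02 (percentile 27.5) and -0.05 (percentile 1.53), mitochondrially encoded proteins -0.07 (percentile 49.8), -0.03 (percentile 29.6) and 0.06 (percentile 85.6), and nuclear oxidative phosphorylation genes -0.21 (percentile 24.7), -0.03 (percentile 24.9) and -0.03 (percentile 13.9), with none of 60, 8 and 29 members past the rule. Mitochondrial biogenesis and dynamics genes stood at -0.39 (percentile 3.30), -0.11 (percentile 6.08) and -0.00290 (percentile 42.3), with TFB2M lower at 10 min (2.05-fold). Apoptosis regulators stood at -0.11 (percentile 43.9) and 0.02 (percentile 61.5) at 10 and 30 min, with BMF higher at 10 min (2.10-fold). Replication-dependent histones, which mostly lack poly(A) tails, stood at 0.07 (percentile 45.8), -0.24 (percentile 8.45) and -0.24 (percentile 8.46), with H2BC5 (2.22-fold) and H2AC6 (2.02-fold) higher at 10 min. Endothelial (median 0.69, percentile 92.0, 0.16, percentile 77.1 and -0.09, percentile 40.2), immune (0.74, percentile 70.6, -1.11, percentile 4.48 and -0.25, percentile 38.3) and epithelial markers (0.04, percentile 55.6, 0.07, percentile 73.4 and 0.02, percentile 62.2) had 5, 3 and 5 measured members, and TIE1 alone passed the rule (2.19-fold higher at 10 min). Housekeeping genes stood at -0.23 (percentile 13.6), 0.04 (percentile 86.1) and 0.05 (percentile 81.2), with B2M lower at 30 min. Of the remaining lists and times, the integrated stress list stood at 0.05 (percentile 93.9) and 0.09 (percentile 97.9), TGF-beta and BMP targets at -0.11 (percentile 52.0) and -0.07 (percentile 6.60) and serum response factor and YAP targets at -0.02 (percentile 70.3) and 0.04 (percentile 83.3) at 10 and 360 min, and only 2 of 10 metallothioneins were measured. ID2 was lower at 10 min (3.23-fold) in the TGF-beta and BMP list. Heat shock genes stood at -0.08 (percentile 8.86) and 0.06 (percentile 87.8) at 30 and 360 min and circadian genes at 0.06 (percentile 76.8) at 360 min, with no member past the rule.

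Loci past the size rule more often had a different leading transcript model in the 2 libraries than loci matched on level and number of models. The ratio of these shares was 1.89 at 30 min (41.7% against 22.0%) and 1.58 at 360 min (41.4% against 26.2%), so sharing of reads among models may contribute to changes such as those of CHP1, SP1 and VAT1. At 10 min the ratio was 1.36, between the bounds set beforehand, and leaves this open. Among loci whose leading model held at least 90% of counts in each library, 11.6%, 3.35% and 1.60% passed the rule at 10, 30 and 360 min. Of the others, 10.6%, 2.95% and 2.23% did, so the share was lower in the first set only at 360 min. The leading model did not have to be the same in each library, and for NSMCE3 at 30 min it differed. These shares were also not matched on level or number of models, so they do not test sharing of reads. True switches of isoform remain open and untested.

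An intercalating drug could slow elongation through long genes, which would lower them most at 360 min. The 2162 longest genes (median length 164587 bases) had a median log2 ratio -0.0234 relative to that of the 2162 shortest (5093 bases), with a bootstrap interval of -0.04 to -0.01, far from the -0.2 that such slowing was set to need. The same difference was 0.12 at 10 min and -0.04 at 30 min.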
